A study of Homo sapiens with 30 samples.

How the data were processed

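Expected counts per gene were taken as deposited, in 2 tables of 23170 genes: 12 libraries of Y79 and SHP77, and 18 libraries of WERI-RB1, NCI-H209 and NCI-H2171. Per the submitters' processing notes, reads were handled with CASAVA 1.8.2, bcl2fastq and FastQC 0.11.7 and counted with RSEM 1.3.0 on GRCh37.p13; the aligner and annotation are not given in the sources used here. Every column was mapped to its sample by name, with 0 left unmapped. The expected counts were rounded to whole counts. Libraries held 13.4 to 28.5 M counts in Y79, 10.1 to 30 M in SHP77, 19.4 to 25.7 M in WERI-RB1, 17 to 22.8 M in NCI-H209 and 19.5 to 29.7 M in NCI-H2171, and 14785 to 17306 genes had counts above 0 in a library. Of the gene symbols, 23 were on more than 1 line of the tables and were kept apart by gene identifier. The gene reference used here was on a later genome build, so no coordinates were used. From it, 22991 symbols were matched by name for gene type. GC content and transcript length came from a separate set of transcript sequences, also matched by name.

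Counts were analysed per line in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM, and genes were kept by filterByExpr (minimum count 10, minimum total 15). A quasi-likelihood fit without a block was used for each line, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A prior count of 0.125 was used for log2 fold changes, and the SE is the absolute log2 fold change divided by the square root of the F statistic. Differences between lines came from a joint fit of each table with a line by vector term. A gene with 0 counts in the reference group was given a floor of 3 counts per library and is reported as at least that fold; a gene with 1 to 3 reference counts is given as a ratio with an exact 95% counting interval. DESeq2 1.42.0 set 18 adjusted p values to NA in NCI-H209 and 2 in NCI-H2171, and these were treated as not passing.

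A fixed set of 23 lists of pathway, cell-type and cell-state genes with 628 members, all found in the tables, was tested by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were alternatives. Members were also counted with adjustment over the list alone. Genes were named by a fixed rule: YAP1, WWTR1 and TEAD1 to TEAD4 in each line; per contrast the 8 largest rises and falls among genes that passed, with a mean of at least 2 CPM and full separation of the groups; up to 4 members per list with the smallest p; 10 shared genes in each direction; and 4 in each direction per difference between lines. Clone names were skipped, as were genes that the gene reference marks as pseudogenes. The text prints a subset of these, and a few genes that meet the rule are not reported here. The comparisons, lists, naming rule, threshold and main settings were fixed before the data were examined.

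Replicate numbers in the library titles were checked as a pairing. Within a line, deviations of each library from its group mean correlated between same-numbered libraries at 0.780 to 0.845 in Y79, 0.796 to 0.837 in SHP77, 0.277 to 0.623 in WERI-RB1, 0.504 to 0.894 in NCI-H209 and 0.430 to 0.753 in NCI-H2171. Pairs of libraries with different numbers gave -0.623 to 0.260 in WERI-RB1, -0.867 to 0.829 in NCI-H209 and -0.590 to -0.0615 in NCI-H2171. In NCI-H209, Empty replicate 1 correlated at 0.829 with 5SA replicate 2 and at 0.504 with 5SA replicate 1, so the replicates 3 stood apart there and numbers 1 and 2 were not shown to be pairs. With 2 libraries per group the deviations are mirror images, so these carry less information in Y79 and SHP77. The labels name no batch, and replicate number as a block was therefore an alternative and not the primary fit. The primary fit leaves any effect shared by a number in the spread between libraries. That spread (biological coefficient of variation) was 0.158 in Y79 and 0.149 in SHP77, against 0.0515 and 0.0379 with the block. In WERI-RB1, NCI-H209 and NCI-H2171 it was 0.180, 0.237 and 0.141, against 0.106, 0.0893 and 0.0665 with the block. If numbers mark a shared effect, the primary fit's counts of changed genes may therefore be too low in all 5 lines.

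The alternatives were RLE and upper-quartile scaling, no filter, a stricter filter of 1 CPM, DESeq2, limma-voom, replicate number as a block, YAP1 left out, an absolute log2 fold change of at least 1, all libraries of a table in 1 fit, and each library left out in turn. In Y79 and SHP77 a leave-out left 1 library in that group, and the other groups supplied the spread. Replicate number was then out of balance with vector, so these leave-outs do not measure the stability of a call. Leaving out rRNA genes, leaving out both NCI-H209 libraries numbered 3, leaving out each library for the differences and overlaps, and the block for the overlaps were added after the data were seen. All tools were tested on simulated data with 50 changed genes at each fold. The simulated counts had a mean per gene and replicate number, with the spread of the blocked fit. An effect of number was thus built in, and recovery and false shares of both fits depend on it. At folds of 1.5, 2, 4 and 8, the primary edgeR fit recovered 6%, 52%, 92% and 94% in Y79, 8%, 52%, 76% and 84% in SHP77, 2%, 50%, 84% and 92% in WERI-RB1, 0%, 18%, 64% and 86% in NCI-H209, and 16%, 66%, 94% and 94% in NCI-H2171. For differences it recovered 0%, 28%, 78% and 88% (Y79 and SHP77) and 4%, 28%, 86% and 94% (WERI-RB1 and NCI-H209). Its false share of calls was 0.901% or less. The blocked fit recovered 80% at a fold of 1.5 in Y79 and 82% in SHP77, but its false share was 9.31% in Y79, 8.42% in SHP77, 9.39% in WERI-RB1, 2.63% in NCI-H209 and 11.1% in NCI-H2171, above the 5% aimed at in all but 1 line. In that order these shares rest on 19, 17, 17, 5 and 23 false calls in a single simulated data set per line. Far fewer genes were changed there than passed with 5SA YAP, so recovery and false shares may differ in those comparisons.

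Overlaps of called genes were compared with the number expected if calls were independent, and 20 simulations of unchanged groups that share libraries were run for the comparisons with shared wild-type libraries. All 10 splits of the 6 libraries of a 5SA line into 3 and 3 were fitted again; 100 combinations for the overlap, which carry little information beyond the splits, and 40 permutations of vector labels for the differences, each including the real labels, were drawn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Read-level processing, transcript-level counts and any distinction of transgene from endogenous YAP1 were not analysed here.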

Results

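RNA was sequenced from 5 human cell lines, 5 days after transduction with a YAP vector or an empty vector, in 30 libraries of 12 groups. The retinoblastoma line Y79 and the small cell lung cancer (SCLC) line SHP77 received wild-type YAP, S94A YAP or the empty vector (n = 2 libraries per group, paired reads of 100 bases). The S94A form cannot bind the TEAD transcription factors. The retinoblastoma line WERI-RB1 and the SCLC lines NCI-H209 and NCI-H2171 received 5SA YAP, which lacks the sites phosphorylated by the LATS kinases, or the empty vector (n = 3 per group, paired reads of 75 bases). Libraries held 10.1 to 30 M expected counts, and rRNA took 0.151% to 9.54% of them. Values after "log2" are log2 fold changes ± SE from edgeR, and levels are counts per mega-count (CPM), mean ± SD over the libraries of a group. The p-values measure only the spread between libraries, because the labels do not say whether libraries came from separate cultures. Expected counts were rounded to whole counts, and intervals and floors on fold changes cover counting error only.

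YAP1 counts rose with every vector that carried YAP. They combine the transgene and the endogenous gene. In Y79, YAP1 went from 0 CPM to 55.5 ± 7.72 CPM with wild-type YAP (at least 462-fold, edgeR adjusted p = 0.00449) and to 66.8 ± 0.888 CPM with S94A YAP (at least 557-fold, edgeR adjusted p = 0.00393), n = 2 per group. The S94A call in Y79 was lost without either S94A library, which left 0 changed genes. In SHP77 it went from 0.304 ± 0.252 CPM to 202 ± 19.5 CPM with wild-type YAP (log2 9.70 ± 0.28, edgeR adjusted p = 0.000656) and to 234 ± 8.54 CPM with S94A YAP (edgeR adjusted p = 0.000577), n = 2 per group. The difference between the wild-type and S94A groups did not pass in Y79 (log2 -0.27, edgeR adjusted p = 0.797) or SHP77 (log2 -0.21, edgeR adjusted p = 0.951). With replicate number as a block it passed in both lines (edgeR adjusted p = 0.0130 and 0.0365), with the lower level in the wild-type group. With 5SA YAP, YAP1 went from 6.86 ± 4.20 to 233 ± 68.3 CPM in WERI-RB1, from 0.0318 ± 0.0551 to 123 ± 60.6 CPM in NCI-H209 and from 0.0628 ± 0.0545 to 326 ± 35.9 CPM in NCI-H2171 (n = 3 per group). The edgeR adjusted p values were 0.000758, 0.000457 and 7.89e-09. Levels were scaled within each line, and the 2 tables were not normalised together, so they rank no line against another.

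**Figure D1:**
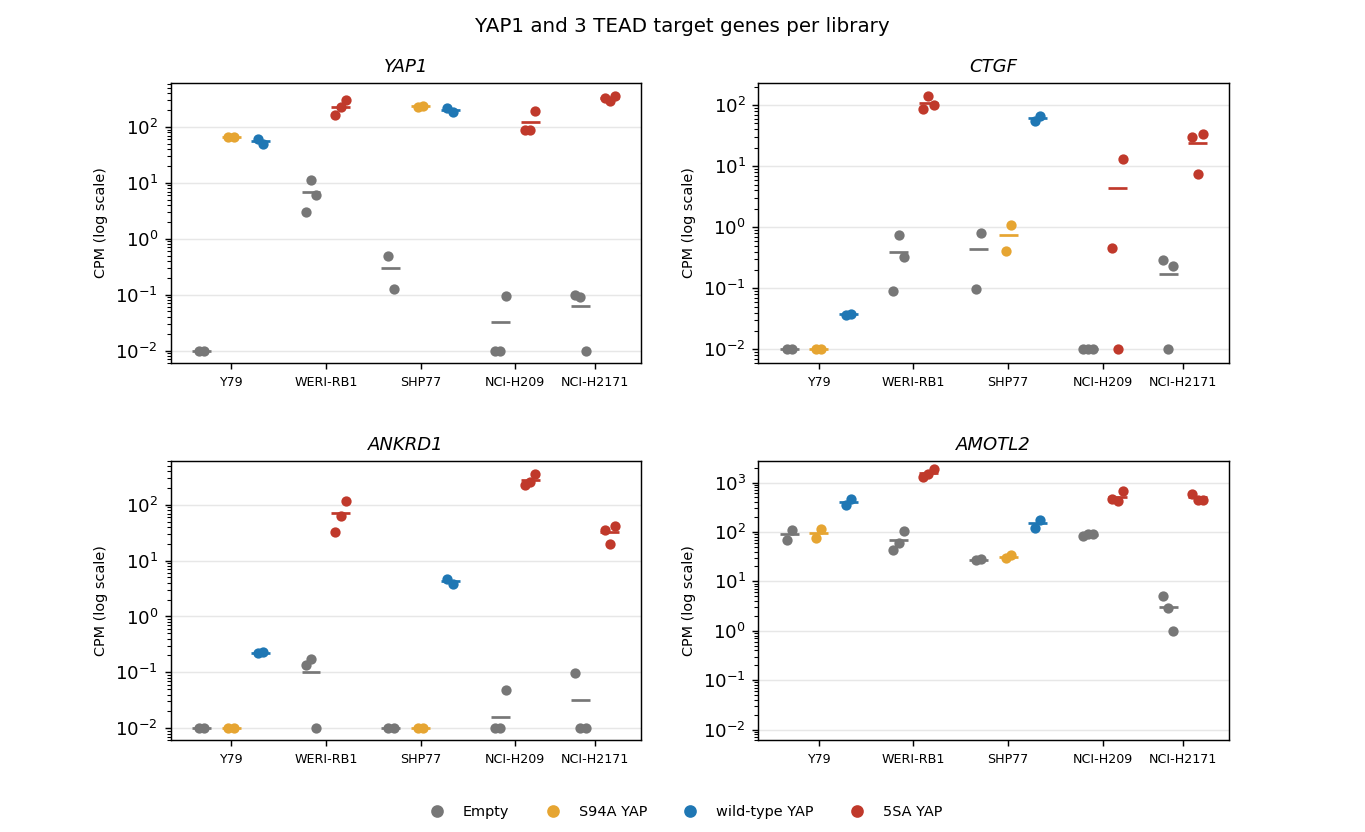
CPM of YAP1, CTGF, ANKRD1 and AMOTL2 (log axis, 0 drawn at 0.01) in every library of the 5 lines, by vector; points are libraries and bars are means. CTGF reached 61.0 CPM with wild-type YAP in SHP77 against 0.744 CPM with S94A YAP.

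Wild-type YAP raised 9 genes in Y79 and lowered 0 of 13209 tested. Besides YAP1 these included PDGFRB, the platelet-derived growth factor receptor of mesenchymal cells (log2 4.94 ± 0.42; 9.32 ± 2.56 against 0.292 ± 0.0741 CPM, n = 2 per group), the carbonic anhydrase CA14 (log2 4.20 ± 0.34; 18.7 ± 6.38 against 1.03 ± 0.238 CPM) and cardiac troponin C, TNNC1 (log2 3.37 ± 0.29). The membrane protein TMEM229A (log2 2.72 ± 0.23) and the JNK-binding protein SH3BP5 (log2 2.50 ± 0.20) rose as well. So did the transcription factor MYRF (log2 2.34 ± 0.19; 107 ± 28.5 against 21.1 ± 1.04 CPM) and the membrane protein EMP2 (log2 1.59 ± 0.11; 237 ± 19.0 against 79.05 ± 6.21 CPM). Each of these had an edgeR adjusted p of 0.0488. The angiomotin AMOTL2, a YAP-binding protein and TEAD target, stood at 408 ± 87.4 against 88.9 ± 27.6 CPM and did not pass (log2 2.20 ± 0.31, edgeR adjusted p = 0.121). It passed with replicate number as a block (edgeR adjusted p = 1.10e-17), as did the membrane repair protein MYOF (log2 4.76, 1.31e-07) and the phosphatase PTPN14, a YAP inhibitor (log2 3.56, 7.89e-07).

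Among fixed gene lists in Y79, the YAP/TEAD target list had 0 of 14 tested members past the threshold over all genes, 4 up and 1 down when adjusted over the list alone, and 8 up and 2 down with the block. The targets CTGF and ANKRD1 reached at most 0.0382 and 0.229 CPM with wild-type YAP. Extracellular matrix genes gave 0 of 30 over all genes, 6 up adjusted over the list alone and 20 up with the block. Focal adhesion and actin genes gave 0 of 35, 8 up and, with the block, 15 up and 2 down. Photoreceptor markers did not move as a group (camera adjusted p = 0.756), although 4 passed upward and 11 downward of 37 with the block; the rod arrestin SAG was among the latter (log2 -1.09, edgeR adjusted p = 0.304, block 0.00273). The camera adjusted p values were 1.89e-06 for targets and 4.48e-11 for matrix genes, and adjusted p = 0.137 with an estimated correlation for both (0.233 for focal adhesion genes). One Y79 library, wild-type replicate 1, held 9.54% rRNA. The block raised the count of changed genes to 2405 (1267 up, 1138 down), DESeq2 gave 164, limma-voom 2 and 1092 genes had nominal p under 0.05. The 8 genes other than YAP1 had adjusted p = 0.0549 in edgeR when YAP1 was left out, and 1 gene passed without Empty replicate 1, Empty replicate 2 or wild-type replicate 1, against 16 without wild-type replicate 2.

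S94A YAP changed only YAP1 in Y79 (1 up, 0 down of 13209). Of the 14 tested YAP/TEAD targets, 0 passed over all genes, adjusted over the list alone or with the block, and their median log2 fold change was -0.0745. With all libraries no list reached a camera adjusted p under 0.32. Each leave-out left 1 library in a group, with the spread taken from the other groups, so list passes in them are no evidence of a stable change. Leaving out any 1 library made the AP-1 and immediate early list pass (camera adjusted p from 9.27e-05 to 0.0181), upward in 2 leave-outs and downward in 2, and the neuroendocrine and TGF-beta lists passed downward in 2 each. Between wild-type and S94A YAP, edgeR called 0 genes in Y79, with 927 at nominal p under 0.05, 132 by DESeq2 and 1892 with the block (1053 up, 839 down). AMOTL2 stood at 408 CPM with wild-type and 95.4 ± 27.4 CPM with S94A YAP (log2 2.10, edgeR adjusted p = 0.2004, block 3.82e-17), and PDGFRB was higher with wild-type YAP at log2 5.62 (edgeR adjusted p = 0.0976). Of the 14 targets, 4 were higher with wild-type YAP when adjusted over the list alone and 7 with the block; of 30 matrix genes, 4 and 18. For fibroblast and stromal markers the median was -0.0793 and the mean 0.758, and the camera direction was up, a call lost with the block (camera adjusted p = 0.0728). The S94A count with the block was 14 (4 up, 10 down). Without wild-type replicate 2, 7 genes passed between the YAP forms.

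In SHP77, wild-type YAP raised 69 genes and lowered 1 of 13562 tested, with YAP/TEAD targets among the rises. CTGF, a secreted matricellular protein, went from 0.447 ± 0.495 to 61.0 ± 8.78 CPM (log2 6.75 ± 0.54, edgeR adjusted p = 0.0149, n = 2 per group), and the ankyrin repeat protein ANKRD1 from 0 to 4.26 ± 0.553 CPM (at least 24.9-fold, edgeR adjusted p = 0.0473), a call lost with the stricter filter (0.0528). The angiomotins AMOT (log2 3.87 ± 0.35) and AMOTL2 (log2 2.43 ± 0.20; 149 ± 39.0 against 27.5 ± 1.38 CPM) rose. The annexin ANXA3 rose by log2 5.29 ± 0.27 (41.6 ± 11.2 against 1.08 ± 0.108 CPM). Matrix genes rose: the integrin-binding TGFBI (log2 4.67 ± 0.38), the lysyl oxidase LOXL2 (log2 1.79 ± 0.10; 79.4 ± 5.65 against 23.0 ± 0.985 CPM), thrombospondin 1, THBS1 (log2 2.35 ± 0.23), and laminin gamma 1, LAMC1 (log2 0.72 ± 0.07; 371 ± 19.8 against 224 CPM). The urokinase PLAU (log2 2.58 ± 0.16), keratin 80, KRT80 (log2 4.12 ± 0.31), the tight junction claudin CLDN1 (log2 4.06 ± 0.39) and the TWEAK receptor TNFRSF12A (log2 2.61 ± 0.15) rose too, as did the interferon-induced membrane proteins IFITM3 (log2 1.89 ± 0.10) and IFITM2 (log2 1.53). The chaperone CLU (log2 2.54 ± 0.25) and the stress cytokine GDF15 (log2 1.78 ± 0.15) rose, with edgeR adjusted p values of 0.0253 and 0.0173. The only gene that fell was the imprinted retrotransposon-like gene RTL1 (77.1 ± 2.12 against 139 ± 9.83 CPM, log2 -0.85 ± 0.08, edgeR adjusted p = 0.0247).

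In the SHP77 lists, 3 of 16 tested YAP/TEAD targets rose over all genes, 7 adjusted over the list alone and 9 with the block (camera adjusted p = 1.37e-26). Matrix genes gave 7 of 31 up, 13 adjusted over the list alone; focal adhesion genes 5 of 35 and 17; epithelial-mesenchymal genes 1 of 18 and 6; and interferon response genes 2 of 20 and 2. With an estimated correlation the camera adjusted p values were 0.0154, 0.0154, 0.0231, 0.0355 and 0.0416 in that order. No G1/S or G2/M gene passed over all genes, but with the block 20 of 38 G1/S genes and 27 of 36 G2/M genes passed downward, including the mitotic kinase AURKB (log2 -0.37, edgeR adjusted p = 2.77e-05 with the block). Those lists had camera adjusted p = 7.04e-11 and 1.78e-15, and adjusted p = 0.0845 and 0.116 with an estimated correlation. Neuroendocrine markers did not move as a group (camera adjusted p = 0.419); gastrin-releasing peptide, GRP, passed downward only with the block (log2 -0.67, edgeR adjusted p = 9.07e-11). The block raised the count to 1818 (1139 up, 679 down), DESeq2 gave 221 and limma-voom 71. Leaving out a library left 1 in its group and set replicate number out of balance with vector. The stability of these calls cannot be judged from it. The count fell to 1 without Empty replicate 1 or 2, to 8 without wild-type replicate 1 and to 19 without wild-type replicate 2, and of 26 named genes only YAP1 passed in each of these.

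S94A YAP changed only YAP1 in SHP77, and none of the targets that rose with wild-type YAP passed. CTGF was 0.744 ± 0.474 CPM with S94A YAP (Empty 0.447 CPM), AMOTL2 31.5 CPM (27.5 CPM; log2 0.19 ± 0.19) and LOXL2 changed by log2 -0.19. Of 16 tested targets 0 passed over all genes, adjusted over the list alone or with the block. Wild-type against S94A YAP raised 62 genes and lowered 1: CTGF by log2 6.37 ± 0.50 (edgeR adjusted p = 0.0150), ANKRD1 at least 30.2-fold (0.0434), ANXA3 by log2 4.94 (0.00520), TGFBI by log2 4.75, AMOT by log2 4.53, the synaptotagmin SYT12 by log2 4.07 (0.0282), the scaffold protein AHNAK by log2 3.99 (0.0241), KRT80 by log2 3.70, AMOTL2 by log2 2.24 (0.0192) and LOXL2 by log2 1.99 (0.00441). IFITM3 (log2 1.85) and TNFRSF12A (log2 2.21) were also higher, and RTL1 was lower (log2 -0.72, 0.0350). Targets gave 3 of 16 up (7 adjusted over the list alone) and matrix genes 7 of 31 (14); camera adjusted p = 0.0146 for each with an estimated correlation. The rises against Empty and against S94A shared 60 genes, against 0.315 expected if the comparisons were independent. In 20 simulations of unchanged groups that share the wild-type libraries, 0 genes were called in both and 3.80 on average (highest 7) had nominal p under 0.05 in both. Those simulations hold no changed genes, and an effect of replicate number was built into them. They do not measure what the shared libraries add to real effects, so part of the excess may come from those libraries. With the block 1939 genes passed (1238 up, 701 down) and DESeq2 gave 202. Without S94A replicate 1 or 2 no gene passed, without wild-type replicate 1, 6, and without wild-type replicate 2, 19. S94A YAP against Empty gave 12 genes with the block (4 up, 8 down), and G2/M genes had camera adjusted p = 6.49e-07 downward with 0 members called and adjusted p = 0.918 with an estimated correlation; that call was lost without Empty replicate 2 (0.267) or S94A replicate 1 (0.378). The AP-1 and immediate early list did not pass with all libraries but passed in each of the 4 leave-outs (1.70e-07 to 0.000796), in opposite directions.

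The wild-type YAP effect differed between Y79 and SHP77 for 24 of 14781 genes, 12 higher in each line. CA14 rose more in Y79 than in SHP77 (log2 4.20 and -0.09; edgeR adjusted p = 0.00748 for the difference). For keratin 18, KRT18, the effect was higher in Y79 (log2 5.21, against 0.36 in SHP77; edgeR adjusted p = 0.0491 for the difference), but KRT18 passed in neither line alone, and the difference was lost without a filter (0.0979) and in limma-voom (0.124). KRT80 (log2 0.01 in Y79, 4.11 in SHP77), the lysyl oxidase LOXL4 (log2 -0.21 and 2.82) and the ephrin receptor EPHA2 (log2 0.38 and 3.12; edgeR adjusted p = 0.0491) rose more in SHP77. The EPHA2 difference was lost with upper-quartile scaling (0.0506), without a filter (0.0627) and in limma-voom (0.369), and the KRT80 difference in limma-voom (0.0828). In the fit without a block, only YAP1, which the vector delivered to both lines, passed upward in both. With the block 265 genes passed upward in both (77.5 expected) and 103 downward (51.1 expected). The S94A effect differed for 0 genes by edgeR and DESeq2 (164 with nominal p under 0.05; 2 with the block). With the block 1129 genes differed for wild-type YAP and DESeq2 gave 105. None of the 8 genes named by rule passed in every leave-out: the count was 0 without Y79 Empty replicate 1 or SHP77 Empty replicate 2, 2 without SHP77 wild-type replicate 1, 7 without Y79 Empty replicate 2 or SHP77 Empty replicate 1, 10 without Y79 wild-type replicate 1, 11 without SHP77 wild-type replicate 2 and 38 without Y79 wild-type replicate 2. For the shared genes, DESeq2 gave 19, and 2 passed without Y79 wild-type replicate 2.

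5SA YAP raised 2043 genes and lowered 1398 of 14863 in WERI-RB1, with YAP/TEAD targets rising and photoreceptor genes falling. Of the targets, the matricellular proteins CTGF (0.386 ± 0.334 to 109.7 ± 28.1 CPM, log2 8.14 ± 0.44, n = 3 per group) and CYR61 (1.12 ± 0.371 to 161 ± 37.8 CPM, log2 7.17 ± 0.30) rose, with edgeR adjusted p values of 9.17e-05 and 2.98e-05. So did ANKRD1 (0.103 ± 0.0918 to 70.1 ± 41.7 CPM, log2 9.38 ± 0.78), the BMP-binding protein CRIM1 (log2 5.23 ± 0.30) and the LATS2 kinase, which phosphorylates YAP (log2 4.59 ± 0.27). The WNT and BMP antagonist SOSTDC1 was at 10.52 ± 0.932 CPM against 0 (at least 81.8-fold, edgeR adjusted p = 0.000115), and the mesenchymal cadherin CDH11 rose from 1.002 ± 0.175 to 202 ± 37.3 CPM (log2 7.65 ± 0.22, edgeR adjusted p = 6.59e-06). The protocadherin PCDH7 rose by log2 8.14 ± 0.53. TEAD1 itself rose (203 ± 12.5 to 447 ± 50.6 CPM, log2 1.14 ± 0.11, edgeR adjusted p = 0.000594), as did TEAD4 (log2 1.17, 0.00746), while WWTR1, encoding TAZ, did not pass (log2 -0.25, edgeR adjusted p = 0.592). Of 20 tested targets 17 rose (18 adjusted over the list alone), with a median log2 fold change of 3.10.

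Matrix and adhesion genes rose in WERI-RB1: 25 of 44 matrix genes rose and 1 fell (27 and 1 adjusted over the list alone), and 27 of 44 focal adhesion and actin genes rose (29). Fibrillin FBN1 (log2 3.80 ± 0.25; 55.6 ± 14.3 against 3.99 CPM), collagen COL1A1 (log2 1.803 ± 0.16), laminin LAMB2 (log2 1.35), the metalloproteinase inhibitor TIMP3 (log2 2.81), the actin crosslinker FLNA (931 ± 124 to 3028 ± 135 CPM, log2 1.70 ± 0.12) and parvin PARVA (log2 2.56) were examples. Keratin 8, KRT8, rose by log2 5.51 (373 ± 199 against 8.21 CPM) and claudin CLDN1 by log2 3.90; 8 of 18 keratin and junction genes rose and 1 fell. With an estimated correlation no list here passed: the camera adjusted p values were 0.248 for targets, 0.315 for matrix, 0.296 for focal adhesion and 0.315 for keratin and junction genes. The ganglion cell factor POU4F2 rose by log2 2.22 ± 0.17 (171 ± 14.5 against 36.8 ± 8.21 CPM); the list of other retinal cell markers that holds it gave 7 up and 1 down of 19 (camera adjusted p = 0.0487, 0.204 with the block and 0.296 with an estimated correlation).

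Photoreceptor markers fell in WERI-RB1: 29 of 41 tested fell and 0 rose (34 fell adjusted over the list alone), with a median log2 fold change of -1.29 (camera adjusted p = 2.32e-20, and adjusted p = 0.248 with an estimated correlation). The rod transcription factor NRL went from 51.7 ± 37.3 to 2.06 ± 0.662 CPM (log2 -4.63 ± 0.58, edgeR adjusted p = 0.00192), rod arrestin SAG from 11.5 ± 1.32 to 0.917 ± 0.632 CPM (log2 -3.61 ± 0.42, 0.00124) and the axoneme protein RP1 from 75.4 ± 21.5 to 7.57 ± 4.23 CPM (log2 -3.30 ± 0.41, 0.00187). Cone arrestin ARR3 (log2 -2.98 ± 0.28), cone transducin GNGT2 (log2 -2.06 ± 0.15), recoverin RCVRN (log2 -1.74 ± 0.17) and the trafficking protein UNC119 (log2 -1.82 ± 0.19) fell too. MYCN, the MYC family gene often amplified in retinoblastoma, fell from 334 ± 20.7 to 80.3 ± 19.3 CPM (log2 -2.06 ± 0.17, edgeR adjusted p = 0.000333) while MYC rose (11.1 ± 3.08 to 38.2 ± 10.3 CPM, log2 1.77 ± 0.26, 0.00284). G1/S genes fell, 20 of 38 (24 adjusted over the list alone), for example the DNA repair enzyme UNG (log2 -0.69) and the phosphatase CDC25A (log2 -0.58), with camera adjusted p = 1.99e-06 and adjusted p = 0.296 with an estimated correlation. Of 36 G2/M genes, 5 fell.

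**Figure D2:**
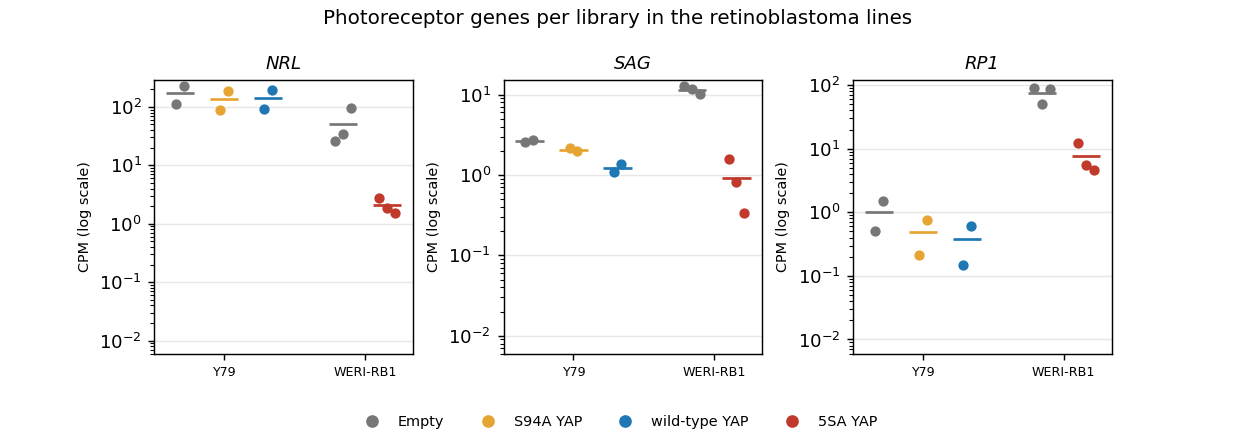
CPM of NRL, SAG and RP1 (log axis) in each Y79 and WERI-RB1 library by vector; points are libraries and bars are means. NRL stood at 2.06 CPM with 5SA YAP and 51.7 CPM with the empty vector in WERI-RB1.

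Neuroendocrine markers split in WERI-RB1, with 5 up and 5 down of 34; the neuronal tubulin-binding gene STMN2 rose (log2 1.90) and the adhesion gene NCAM1 fell (log2 -0.72). The changed count of 3441 was 5781 with the block (3053 up, 2728 down), 4077 by DESeq2 and 1470 at an absolute log2 fold change of at least 1. It was 1706 without 5SA replicate 2 and 1966 without Empty replicate 2. Over the other splits of the 6 libraries 0 genes passed, and lists past the threshold numbered 13 in the real split and up to 15 in others. Each other split put 5SA and Empty libraries in both groups, so the 5SA effect widened the spread there. Neither count is therefore a clean null, and the list count did not stand above that of the other splits.

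In NCI-H209, 5SA YAP raised 730 genes and lowered 150 of 14027, with YAP/TEAD targets among the rises. ANKRD1 went from 0.0159 ± 0.0276 to 284 ± 71.9 CPM (ratio 17894, counting interval 3211 to 7.07e+05; edgeR adjusted p = 6.77e-05, n = 3 per group). PTPN14 (log2 5.33 ± 0.18; 58.2 ± 5.84 against 1.44 ± 0.224 CPM), LATS2 (log2 4.33 ± 0.25), AMOT (log2 4.39 ± 0.17; 168 ± 29.1 against 8.03 ± 0.395 CPM) and MYOF (log2 6.47) rose. TEAD4 (log2 2.14 ± 0.29, edgeR adjusted p = 0.00719) and WWTR1 (log2 2.97 ± 0.41; 5.90 ± 2.62 against 0.749 ± 0.205 CPM, 0.00743) rose; TEAD1 did not pass (log2 0.41, edgeR adjusted p = 0.499; block 4.70e-05). The calcium-dependent protease family member CAPN6 (75.02 ± 30.8 CPM against 0, at least 529-fold), the lectin receptor OLR1 (at least 135-fold), the TEAD cofactor VGLL1 (at least 129-fold) and annexin ANXA1 (log2 10.32 ± 0.39; 88.7 ± 1.91 against 0.0613 CPM) were among the other rises named by rule, as was keratin KRT4 (at least 64.0-fold). Of 18 tested targets, 12 rose (15 adjusted over the list alone; 18 with the block). The list holds 22 targets, and those not tested are outside these counts. CTGF stood at 0.456, 0 and 12.9 CPM in 5SA replicates 1, 2 and 3.

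Matrix genes rose in 18 of 35 tested in NCI-H209 (26 up and 1 down adjusted over the list alone) and focal adhesion genes in 20 of 42 (27). The matrix proteins SPARC (log2 8.32 ± 0.24; 185 ± 29.3 against 0.575 ± 0.144 CPM), fibronectin FN1 (log2 7.77 ± 0.27), FBLN5 (log2 4.76; 116 ± 26.4 against 4.26 CPM) and agrin AGRN (log2 3.81) rose, as did the actin-binding protein CALD1 (log2 9.32) and integrins ITGB5 (log2 4.23 ± 0.23) and ITGB4 (log2 2.69). The NOTCH pathway rose in 8 of 19 (10 up and 2 down adjusted over the list alone): NOTCH2 (log2 3.78 ± 0.15; 126 ± 8.59 against 9.15 ± 1.20 CPM), the repressor HES1 (log2 5.65 ± 0.32), the ligase DTX4 (log2 2.65) and the coactivator MAML2 (log2 2.37). The TGF-beta receptor TGFBR2 (log2 3.29), the cell cycle inhibitor CDKN2B (log2 1.79) and keratin KRT80 (log2 2.13) rose. With an estimated correlation the camera adjusted p values were 0.0112 for targets, 0.00851 for matrix, 0.0112 for NOTCH and 0.0540 for focal adhesion genes.

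Falls in NCI-H209 were fewer than rises. Secretogranin SCG2 fell by log2 -2.23 ± 0.20 (120 ± 4.80 to 25.4 ± 6.95 CPM, edgeR adjusted p = 0.00154), potassium channels KCNA1 (log2 -2.49 ± 0.25) and KCNH6 (log2 -2.50 ± 0.31), the membrane protein MS4A8 (log2 -2.84 ± 0.22), the neuronal protein TMEM132D (log2 -2.47 ± 0.14), the transcription factor ST18 (log2 -2.34 ± 0.23) and the homeobox gene PROX1 (log2 -1.05 ± 0.11). Of 34 neuroendocrine markers 1 rose and 2 fell (1 and 7 adjusted over the list alone, 1 and 19 with the block; camera adjusted p = 4.17e-05, adjusted p = 0.363 with an estimated correlation). Cell cycle genes did not pass over all genes; with the block 20 of 36 G2/M genes passed downward. The 880 changed genes became 3266 with the block (1940 up, 1326 down) and 1420 by DESeq2. The rRNA shares of the replicate 3 libraries were 4.12% and 3.93%, and without both of them 2811 genes passed. Without Empty replicate 1 or 2 the count was 471 or 473, and without 5SA replicate 1 or 2, 446 or 538. Of 82 named genes that passed, 20 lost their call in some leave-out. Up to 2 genes passed in other splits of the libraries; 15 lists did so in another split, against 14 in the real split.

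In NCI-H2171, 5SA YAP raised 1695 genes and lowered 733 of 14471. MYOF (log2 4.59 ± 0.16; 72.0 ± 8.01 against 2.99 ± 0.524 CPM, n = 3 per group), LATS2 (log2 3.41 ± 0.19), PTPN14 (log2 3.22 ± 0.19), the kinase NUAK2 (log2 2.09 ± 0.13) and AMOT (log2 5.15 ± 0.15; 314 ± 13.8 against 8.85 ± 1.62 CPM, edgeR adjusted p = 5.30e-08) rose, and ANKRD1 reached 32.3 ± 11.2 CPM (ratio 1052, counting interval 291 to 8691). The retinol-binding protein RBP2 (26.6 ± 3.22 CPM against 0, at least 194-fold), the ankyrin repeat gene ANKRD2 (at least 129-fold) and collagen COL5A3 (log2 9.14) were among the rises named by rule. TEAD1 (log2 1.40 ± 0.12; 137 ± 7.62 against 52.2 ± 6.98 CPM), TEAD3 (log2 0.89) and TEAD4 (log2 0.99) rose. Of 18 tested targets 16 rose (16 adjusted over the list alone). Matrix genes rose in 23 and fell in 2 of 34, for example tenascin TNC (log2 2.00 ± 0.13; 244 ± 31.4 against 61.1 ± 7.41 CPM), FN1 (log2 2.04 ± 0.13) and laminin LAMB3 (log2 2.84). Integrins rose in 10 of 15, including ITGB5 (log2 3.86 ± 0.24) and ITGA6 (log2 1.20), and focal adhesion genes in 25 of 40 with 1 fall, including tropomyosin TPM1 (log2 2.36 ± 0.13; 532.2 ± 76.8 against 104 ± 12.3 CPM) and ANXA3 (log2 6.50 ± 0.20).

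Epithelial-mesenchymal genes rose in 18 and fell in 1 of 23 in NCI-H2171. Keratin KRT17 (log2 6.84 ± 0.45), KRT80 (log2 4.22), the metalloproteinase MMP14 (log2 1.67 ± 0.09) and WNT5A (log2 5.37) rose. REST, a repressor of neuronal genes, rose from 0.265 ± 0.117 to 7.18 ± 0.756 CPM (log2 4.73 ± 0.31, edgeR adjusted p = 4.99e-06). NOTCH2 rose (log2 6.21 ± 0.44) while NOTCH1 fell (log2 -1.09 ± 0.12; 238 ± 36.2 to 112 ± 7.92 CPM, 0.000155). Neuroendocrine markers went both ways, 5 up and 3 down of 36 (camera adjusted p = 0.919): the prohormone convertase PCSK2 rose (log2 3.21 ± 0.32) and the RNA-binding ELAVL4 fell (log2 -1.34 ± 0.15). The cell cycle inhibitor CDKN1A rose (log2 1.39 ± 0.17; 267 ± 2.69 against 102 ± 26.9 CPM, edgeR adjusted p = 0.000251). Of 36 G2/M genes 8 fell, and of 38 G1/S genes 4 fell and 1, TK1, rose. The myosin-family locus MYH16, a pseudogene in humans (log2 -4.34 ± 0.41), the deaminase family gene APOBEC2 (log2 -2.79 ± 0.21) and kinesin KIF19 (log2 -2.73 ± 0.25) were among the falls named by rule. With an estimated correlation the camera adjusted p values were 0.0341 for targets, 0.0341 for integrins, 0.0613 for matrix and epithelial-mesenchymal genes, 0.0893 for focal adhesion, 0.144 for G1/S and 0.592 for G2/M genes. The count was 5632 with the block (2994 up, 2638 down), 2761 by DESeq2 and 1075 at an absolute log2 fold change of at least 1; leaving out 1 library gave 1791 to 2380. Over the other splits 0 genes passed, and 12 lists did in the highest, against 10 in the real split.

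Across the 3 lines given 5SA YAP, 227 genes rose in all (7.21 expected if independent) and 6 fell in all (0.397 expected), of 12654 tested in every line. ANKRD1 was among them, with the log2 value and ratios given above, and ANXA1 rose by log2 5.11 in WERI-RB1, 10.32 in NCI-H209 and 7.12 in NCI-H2171. The sodium-glucose transporter SLC5A1 rose too (ratio 455, counting interval 81.2 to 18005, in WERI-RB1; ratio 148, counting interval 26.1 to 5878, in NCI-H209; log2 5.02 in NCI-H2171). Cardiac troponin T, TNNT2 (log2 7.31, 6.64, 5.98), CALD1 (log2 2.12, 9.32, 5.90) and MYOF (log2 5.64, 6.47, 4.59) were shared. Falls were smaller, and the potassium channel KCNH6 (log2 -1.34, -2.50, -0.99) was the only one of the 6 shared falls that also passed in every leave-out of each line. Pairwise, 335 rises were shared by WERI-RB1 and NCI-H209 (79.6 expected), 683 by WERI-RB1 and NCI-H2171 (198 expected) and 381 by NCI-H209 and NCI-H2171 (64.7 expected). With the block 651 rose and 215 fell in all 3 lines, against 60.3 and 37.0 expected. The count of 233 was 106 at adjusted p under 0.01, 130 at an absolute log2 fold change of at least 1, 145 without NCI-H209 5SA replicate 1, 146 without its Empty replicate 1 and 152 without its Empty replicate 2.

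The 5SA effect differed between lines for 1326 of 16266 genes between WERI-RB1 and NCI-H209 (681 higher in WERI-RB1), 1452 between WERI-RB1 and NCI-H2171 (668 higher in WERI-RB1) and 657 between NCI-H209 and NCI-H2171 (283 higher in NCI-H209). The calcium-binding protein S100A16 rose only in NCI-H209 (7.77 ± 3.10 against 0.0159 CPM, 1 count in Empty; log2 -0.23 in WERI-RB1 and -0.37 in NCI-H2171; edgeR adjusted p = 1.95e-07 and 1.42e-06 for the differences). SPARC rose more in NCI-H209 than NCI-H2171 (log2 8.30 and 1.03; edgeR adjusted p = 2.74e-07), and the sphingomyelinase SMPD3 rose in WERI-RB1 and fell in NCI-H209 (log2 4.66 and -1.70; edgeR adjusted p = 8.02e-08). Among lists, the photoreceptor effect was higher in NCI-H209 than WERI-RB1 for 7 of 41 members and in NCI-H2171 for 10 of 41 (camera adjusted p = 0.000138 and 1.93e-05, and adjusted p = 0.495 and 0.637 with an estimated correlation). Some members had almost no counts in these SCLC lines: RP1 stood at 0 CPM in every library, and SAG at 0.0972 CPM or less. A gene without counts cannot fall, so the difference in part reflects which line expresses these genes. NOTCH genes rose more in NCI-H209 than WERI-RB1 for 8 of 21 members and 0 the other way (camera adjusted p = 2.16e-05, adjusted p = 0.0796 with an estimated correlation). With the block 3568, 3962 and 1989 genes differed in the order above, and DESeq2 gave 1821, 1887 and 941.

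**Figure D3:**
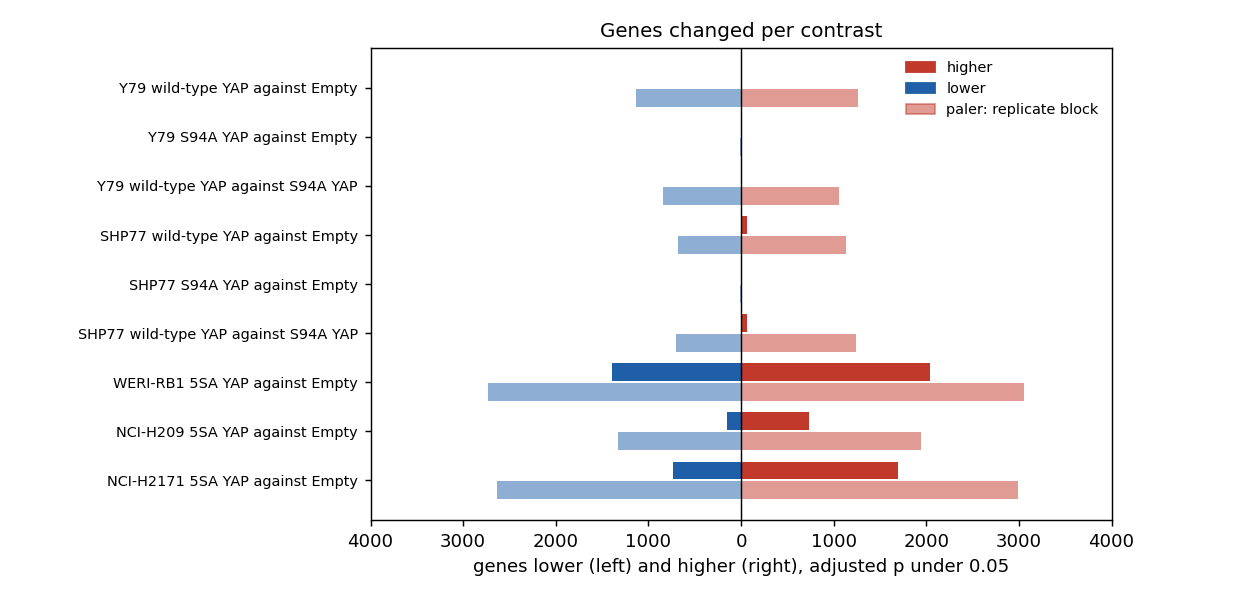
Number of genes changed in each of the 9 comparisons within a line (bars, up and down), with paler bars for replicate number as a block. The counts ran from 0 for wild-type against S94A YAP in Y79 to 3441 in WERI-RB1.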

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

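The tests of the separate pattern explanations below had their limits set before the values were seen, except the test of a lower share of photoreceptor-like cells and the gene set of the replicate-number tests, which were chosen only after results had been seen.

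Counts of genes whose YAP effect differs between lines drew attention because each line was given the same vector: 24 between Y79 and SHP77 with wild-type YAP, 1326 between WERI-RB1 and NCI-H209, 1452 between WERI-RB1 and NCI-H2171, and 657 between NCI-H209 and NCI-H2171 with 5SA YAP. For Y79 and SHP77 the differences named by rule (log2, Y79 minus SHP77) were KRT18 4.85, CA14 4.30, DAB2 3.12 and CDK14 2.81 upward, and KRT80 -4.10, LOXL4 -3.03, EPHA2 -2.74 and HHAT -2.00 downward. With 2 libraries per group none of the 8 passed in every leave-out, and in limma-voom KRT18, DAB2 (0.154), KRT80 and EPHA2 lost their calls.

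Between the lines given 5SA YAP, the differences named by rule include genes with 0 counts in 1 of the groups compared. Their log2 values are set by the prior count and measure neither a size nor a rank: SOSTDC1 (0 in WERI-RB1 Empty), COMMD3-BMI1 (WERI-RB1 5SA), CSH1 (NCI-H209 and NCI-H2171 Empty), ANO2, CAPN6 and VEPH1 (NCI-H209 Empty), and SDPR, LNX1 and FAM3B (NCI-H2171 Empty). Within a line the floors were at least 81.8-fold for SOSTDC1, at least 77.8-fold (NCI-H209) and 93.7-fold (NCI-H2171) for CSH1 and at least 529-fold for CAPN6. The CSH1 call within NCI-H209 did not hold in every leave-out. S100A16 rests on 1 count in NCI-H209 Empty, so its log2 values are not exact sizes either.

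Between WERI-RB1 and NCI-H209 the genes named included SOSTDC1 9.52, KL 7.14, SMPD3 6.36, RALYL 6.03, CSH1 -10.23, S100A16 -8.73 and ANO2 -8.55. CSH1 had an edgeR adjusted p of 0.0434 and lost its call without WERI-RB1 Empty replicate 2 (0.274) or replicate 1 (0.11). Between WERI-RB1 and NCI-H2171 they included SOSTDC1 10.08, CDH6 7.86, SNCAIP 7.16, CDH11 6.65, CSH1 -10.44, COMMD3-BMI1 -9.46 and SDPR -9.17. CSH1 lost its call in most leave-outs (0.259 without WERI-RB1 Empty replicate 2), CDH6 without any NCI-H2171 library (up to 0.171), SOSTDC1 without NCI-H2171 Empty replicate 1, and COMMD3-BMI1 without any WERI-RB1 5SA library, WERI-RB1 Empty replicate 2 or NCI-H2171 5SA replicate 3, and with no filter on low counts (0.0538). COMMD3-BMI1 is a readthrough gene whose counts are uncertain. Between NCI-H209 and NCI-H2171 they were CAPN6 11.99, S100A16 8.87, VEPH1 8.02, SPARC 7.28, ARPP21 -6.18, LNX1 -5.88, OLFML2B -5.78 and FAM3B -5.69; CAPN6 (0.240 without NCI-H2171 Empty replicate 1), ARPP21 (0.0837 without NCI-H209 Empty replicate 1) and LNX1 (up to 0.121) lost their calls in leave-outs.

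Whether the counts could come from how libraries fell into groups was tested by refitting other splits and permutations. Within a line, the 10 splits cannot give a share under 0.05. The real split gave 3441, 880 and 2428 changed genes in WERI-RB1, NCI-H209 and NCI-H2171, and the highest other split 0, 2 and 0, so 1 of 10 splits reached the real count in each line, and among the splits that part all pairs the highest other was 0 with and without the block. For gene lists, 2 of 10 splits reached the real count in WERI-RB1 (13 lists, highest other 15), 3 of 10 in NCI-H209 (14, highest other 15) and 3 of 10 in NCI-H2171 (10, highest other 12); chance cannot be told apart there. Combinations of these splits say little more about the 233 shared genes, since splits other than the real ones called at most 2 genes in a line.

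For the differences, 40 permutations of the labels within each line were drawn. The count for WERI-RB1 and NCI-H209 was reached in 2 of 40 (real 1326, highest other 1521), and for WERI-RB1 and NCI-H2171 in 2 of 40 (real 1452, highest other 2747). By the limit set in advance these counts could come from the grouping. Those higher draws kept or swapped the real groups of a line, so they carry its own effect and are no clean null; with labels mixed in both lines at most 1 gene differed. For NCI-H209 and NCI-H2171 only the real labels reached 657 (1 of 40, highest other 368), while 308 genes differed in a draw with both lines mixed.

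The libraries that share a replicate number deviated together in Y79 and SHP77. A batch per number across both lines is a candidate explanation: the difference between numbers 1 and 2 correlated over 9788 genes between the lines at 0.497. GC content and transcript length explained at most 5.39% of the variance, so they account for little of it. Without rRNA genes the lowest correlation of same-numbered libraries was 0.798. The few rRNA genes are a small part of the genes correlated, so their removal could hardly change this value. It cannot show whether other genes shifted along with the rRNA share. Over all 11965 tested genes, the set looked at earlier, the values were 0.362, 3.69% and 0.557, on the same side of each limit.

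CSH1, a placental hormone gene, appeared with 5SA YAP in NCI-H209 (10.9 ± 6.12 CPM) and NCI-H2171 (13.2 ± 1.61 CPM), with 0 counts in Empty. Mixed-in placental RNA cannot be told apart from a change in the cells: the median placental gene stood at 1.001% of the CSH1 level in the highest library, against a limit of 1% for each line. Of the 40 placental genes 14 had no count in NCI-H209 and 13 in NCI-H2171. In NCI-H2171 the highest median was 0.0505 CPM and CSH1 was at least 12.3 CPM, under that limit, and ADAM12 (12.4 CPM, 12.3 in Empty) and PAPPA (10.3 CPM, 10.4 in Empty) were near their Empty level. PLAC1 and KISS1 rose there. In NCI-H209 ERVW-1 (3.17 CPM, 2.99 in Empty) and PRG2 (1.81 CPM, 1.84 in Empty) were near theirs, while KISS1 and XAGE2 rose. By the limit set in advance, reads shared among paralogs cannot be told apart either. The CSH1 share of CSH1 and CSH2 counts was 54.4% to 56.5% in NCI-H209 and 65.7% to 72.4% in NCI-H2171. The gap was 9.21 points, which argues against the same division of reads in both lines. Counting intervals overlapped only between NCI-H209 5SA replicate 2 (up to 63.9%) and NCI-H2171 5SA replicate 3 (from 61.2%).

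The photoreceptor fall in WERI-RB1 held under RLE and upper-quartile scaling, where 29 members fell. After the trend on GC content, length and expression was removed, the list median (-1.44) lay at percentile 0 of the 10000 random lists, whose lowest median was -0.41. A lower share of photoreceptor-like cells with the same fall in every marker was weighed too: the members differed from their shared mean with a chi-square over degrees of freedom of 11.3, which excludes that uniform form only.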

How the results depend on the processing

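A count is said to move where it changed by more than 1.5-fold. Replicate number as a block moved every count: Y79 wild-type YAP 2405, S94A YAP 14 and wild-type against S94A 1892; SHP77 1818, 12 and 1939; WERI-RB1 5781, NCI-H209 3266, NCI-H2171 5632. Differences became 1129 (Y79 and SHP77, wild-type YAP), 2 (S94A), 3568, 3962 and 1989, and overlaps 866 (3 lines) and 368 (Y79 and SHP77). Of 405 called named genes only FOSL2 in NCI-H209 lost its call with the block (edgeR adjusted p = 0.139), and of 90 list calls 7 did.

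DESeq2 gave 164, 132, 221, 202 and 1420 genes for Y79 wild-type, Y79 wild-type against S94A, SHP77 wild-type, SHP77 wild-type against S94A and NCI-H209, 105 for the Y79 and SHP77 difference and 19 for their overlap. Limma-voom gave 2 for Y79 wild-type. No filter on low counts gave 23 and 6 for Y79 wild-type against Empty and S94A. One fit of all libraries of a table gave 93, 53 and 1363 (Y79 wild-type, Y79 wild-type against S94A, NCI-H209), kept 343 named-gene calls and lost 30. YAP1 left out gave 0 for Y79 wild-type and for S94A in Y79 and SHP77. At an absolute log2 fold change of at least 1, WERI-RB1 gave 1470, NCI-H2171 1075 and the overlap of 3 lines 130; at adjusted p under 0.01 that overlap was 106. RLE and upper-quartile scaling, the stricter filter and rRNA genes left out moved no count by that much.

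Leaving out 1 library gave 1 to 16 (Y79 wild-type), 0 to 1 (Y79 S94A), 0 to 7 (Y79 wild-type against S94A), 1 to 19 (SHP77 wild-type), 0 to 19 (SHP77 wild-type against S94A), 1706 to 3293 (WERI-RB1), 446 to 869 (NCI-H209), 0 to 38 (Y79 and SHP77 difference), 145 to 242 (overlap of 3 lines) and 1 to 2 (Y79 and SHP77 overlap). Without both NCI-H209 libraries numbered 3 the count was 2811. The leave-outs for differences and overlaps, the block for overlaps, the rRNA alternative and the last were chosen after seeing the data. In Y79 and SHP77 a leave-out left 1 library in a group, so the ranges do not measure stability there.

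The AP-1 and immediate early list changed direction in 8 of its 42 leave-outs, counting those where it passed before or after. Its camera adjusted p ranged from 9.27e-05 to 0.0181 (Y79 S94A), 2.58e-08 to 0.414 (Y79 wild-type against S94A), 7.23e-08 to 0.926 (SHP77 wild-type), 1.70e-07 to 0.000796 (SHP77 S94A) and 1.27e-08 to 0.710 (SHP77 wild-type against S94A). With an estimated correlation 71 of 90 list calls were lost and 28 with fry. The cause of the changes in direction was not tested. They fell in Y79 and SHP77, where each leave-out put replicate number out of balance with vector and same-numbered libraries deviate together. An effect of number and 1 of vector cannot be told apart in those fits. At depths of 10.1 to 30 M a group with 0 counts allows only a floor on a fold; the effect of depth on calls was not tested.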

Other observations

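Muscle and placental genes were among the rises with 5SA YAP, beyond the lists fixed in advance. In NCI-H2171 the muscle genes JPH2, a junctophilin of muscle membranes (ratio 731, counting interval 202 to 6038), and ANKRD2 (at least 129-fold) rose, and cardiac troponin T, TNNT2, rose in all 3 lines (log2 7.31, 6.64 and 5.98 in WERI-RB1, NCI-H209 and NCI-H2171). The natriuretic peptide NPPB reached 50.3 ± 43.5 CPM in WERI-RB1 (ratio 1108, counting interval 379 to 5374; n = 3 per group). The placental genes KISS1 (10.1 ± 3.82 against 0.0157 CPM) and XAGE2 (2.94 ± 0.611 CPM against 0) rose in NCI-H209, and PLAC1 (5.50 ± 0.491 against 0.651 CPM) and KISS1 (3.16 ± 1.18 against 0.155 CPM) in NCI-H2171.

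Interferon-induced membrane genes also rose with 5SA YAP: IFITM2 by log2 5.35 in WERI-RB1 and 3.21 in NCI-H209, and IFITM3 by 4.73 in WERI-RB1, while the chemokine CXCL10 fell in WERI-RB1 (log2 -3.67, edgeR adjusted p = 0.00724). The interferon list gave 3 up and 1 down of 24 in WERI-RB1 (camera adjusted p = 0.361) and 4 up and 1 down of 14 in NCI-H2171 (camera adjusted p = 0.128). In NCI-H209 that list passed by camera, a call lost without 5SA replicate 3 (camera adjusted p = 0.0625). In NCI-H2171 the antigen presentation gene B2M rose (log2 0.95; 634 against 329 CPM). The chaperone CLU rose with YAP in 3 SCLC lines, by log2 2.54 in SHP77, 6.73 in NCI-H209 and 4.54 in NCI-H2171, and by 1.95 in WERI-RB1.

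The hypotheses below were written after some of the largest rises were seen. These were TNNT2, NPPB and JPH2 for muscle, and CSH1, CAPN6 and VGLL1 for placenta. Their limits were set before the list values were seen. KISS1, XAGE2 and PLAC1 did not prompt the placental hypothesis. They are members of its list, from which the genes that prompted it were left out. A rise of striated muscle genes as a group was tested without the genes that prompted it. For this list and the placental list below, p was adjusted over both lists and all 9 comparisons within a line. This is wider than for the fixed lists. The camera adjusted p was 0.152 in WERI-RB1 (9 up and 3 down of 28), 0.811 in NCI-H209 (1 up of 14) and 0.0718 in NCI-H2171 (8 up and 2 down of 24). In NCI-H2171 the unadjusted camera p was 0.0239, so that result depends on how widely p was adjusted. A rise in all 3 lines did not pass, and a rise in WERI-RB1 or NCI-H2171 alone is left open.

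A rise of placental genes as a group cannot be told apart from its absence. The camera adjusted p was 0.00109 in NCI-H209 (2 up of 9) and 0.0501 in NCI-H2171 (2 up of 7). The estimated correlation gave at least 0.253 in both. In NCI-H2171 the unadjusted camera p was 0.0139, so that result too depends on how widely p was adjusted. WERI-RB1, outside that test, had 8 up and 1 down of 14 (camera adjusted p = 0.0295, and adjusted p = 0.409 with an estimated correlation), among them PSG4, PSG9 and CYP19A1. In SHP77 with wild-type YAP the camera adjusted p was 0.00466 against Empty and 0.00633 against S94A (0.257 with an estimated correlation for both), with 0 of 8 members called.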
